A study of Zea mays with 56 samples.

How the data were processed

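Transcripts of single germinal cells from maize anthers were counted. Per the labels' protocols, anthers were treated with protoplasting enzymes, archesporial cell and pollen mother cell protoplasts were told apart from others by size and collected by hand, and libraries followed a modified CEL-Seq2 protocol, in which poly(A) RNA is primed from its 3' end and each molecule carries a unique molecular identifier (UMI) of 10 nt. Per the deposited description, the lysate of each cell was split into 2 tubes that were processed separately, here called the splits of a cell, and library preparation was randomised at several stages. In the metadata the splits of a plant lay in 1 to 6 of the 28 library pools. The series has 56 libraries, which are 28 library pools sequenced in 2 lanes each. A library therefore holds splits of many cells, and none of them stands for a stage.

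The authors deposited 1 table of transcript (UMI) counts, with 31184 features in rows and 391 splits in columns, and the deposited metadata give the plant, the anther length, the pool and the primer barcode of each split. The counts are whole numbers that were not normalised. The submitters' processing notes name CASAVA 1.4, HISAT2 and the maize build B73 RefGen_v4. The counter, the annotation and whether strand was used in counting are not given in the sources used here. The deposited description states 216 cells, and the table holds 206 cells, of which 185 have both splits and 21 have a single split. Of the 391 columns, 9 have no row of the same name in the metadata, and their plant was taken from the row with the same cell number. For 2 columns no pool was known. A further 29 rows of the metadata, 14 of somatic and 15 of unknown origin, were not analysed here. The description advises against 1 primer, and 0 rows of the metadata carry it.

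Features were of 5 kinds by identifier. There were 27243 features with the Zm00001d prefix of maize gene models (62.2% of all UMIs), 3759 with the prefix MSTRG (26.2%), 88 with the prefix GRMZM5G (1.60%), 7 microRNA names (16 UMIs) and 87 ERCC spike-in RNAs (9.96%). The spike-in rows, which name no maize gene, were kept out of library sizes and tests. Their share per split had a median of 9.90% and ranged from 2.39% to 78.7%. The amount of spike-in added is not given in the sources used here. The reference table used here belongs to another assembly (Zm-B73-REFERENCE-NAM-5.0), and 0 of the Zm00001d, 0 of the MSTRG and 0 of the GRMZM5G identifiers matched it, whereas 7 of 7 microRNA names did. The gene lists fixed before the data were examined (meiosis, cell cycle, small RNA pathway, ubiquitin ligase adaptors, cell wall, ribosomal proteins, stress, anther wall and green tissue markers, and MADS transcription factors) had to be resolved by symbol or description, so none could be tested and no marker of another cell type could be looked at. The kinds of identifier were described in their place, a choice made after the data were examined.

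Splits were summed per cell and cells per plant, because cells of a plant are not independent replicates. Plants were put into length classes with borders at 0.5, 1 and 1.5 mm that had been set before the data were examined. Class A (under 0.5 mm) held 3 plants, class B 6 plants, class C 12 plants and class D (1.5 mm or more) 3 plants. Plant 20, with anthers of 2 lengths, was counted once in class D. Class tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr and the quasi-likelihood test (glmQLFit and glmQLFTest), with the 4 classes in 1 fit of 12751 features. The trend test fitted a slope on length in mm over plant sums at each length, with 10840 features. A feature was called at a Benjamini-Hochberg adjusted p below 0.05. The biological coefficient of variation was 0.499. No genotype is named in the metadata, so a comparison of genotypes was not run. Sets of features were tested with camera at a correlation of 0.01 and at an estimated correlation, and with fry, with adjustment over all kinds, comparisons and cell filters tested (limma 3.58.1). DESeq2 1.42.0 was an alternative test.

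The rule for named features, set before the data were examined, took those with the largest change among called features with a mean over 20 CPM in the higher class, every plant of a class above every plant of the other, and a name in the reference. The last condition could not be met, so at most 2 rising and 2 falling identifiers were named for the comparison of classes A and D and for the neighbouring step with the most calls. Both features called from class A to class B were named too, after their values were seen. CPM were computed with TMM-scaled library sizes. A fold against a class with no UMI was computed against a floor of 3 counts over that class. Such floors cover counting error only.

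Cell complexity was measured as the number of features in 5000 UMIs drawn from each cell, and a cell with fewer than 2000 such features is called a cell of low complexity, a border set after the data were examined. The tests were repeated without these cells. Plants 9, 18 and 19 held no other cell, so these repeats had 21 plants, with 10 in class C and 2 in class D. A split held a median of 37821 UMIs, from 850 to 305817, and a cell a median of 77078.5 UMIs, from 5091 to 365087, with a median of 9063 features. Splits of a cell were compared by Pearson's r and Spearman's rho of log2(CPM + 1). Similarity of cells was Spearman's rho across features, tested by a one-sided permutation of cells over plants within class. Relations across plants were tested with two-sided permutation tests of 1e+05 resamples and adjusted over the 6 relations computed. The leading axis was the first principal component of centred log2(CPM + 10) of complex cells with at least 10000 UMIs.

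The tests were tried on simulated counts drawn from the real means and library sizes. Of features changed 8-fold, the class test recovered 83.1% from A to B, 100% from B to C, 62.5% from C to D and 61.5% from A to D, and of features changed 4-fold it recovered 38.8%, 84.7%, 43.9% and 24.2%. Of the calls, 2 of 84, 9 of 128, 1 of 75 and 1 of 57 were false. The trend test recovered 79.7% of features changed 4-fold per mm, with 6 of 77 calls false. These simulated features were drawn independently of each other around a common profile, without library pools and without cells of low complexity. The recovered shares and false calls hold for such counts and need not hold for the real plants. A first version of the statistic for features that vary between cells of a plant failed its simulated test, because the splits of a cell share their depth. It was replaced by a version with every split at 10000 UMIs, which recovered 90, 86 and 93 of 100 varying features in classes A, B and C, with 20, 2 and 3 others.

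Alternatives tried were DESeq2 size factors, library size alone, no filter on low counts, the DESeq2 test, plant and length as the unit, cells with at least 10000 UMIs, cells thinned to 18081 UMIs, library pool as a covariate (limma-voom with plant as a random effect), class borders moved by 0.1 mm and leaving out each plant of classes A and D. Chosen after the data were examined were spike-in totals as library sizes, Zm00001d features alone, cells of at least 2000 features at 5000 UMIs, leaving out each plant of classes B and C, each sum of the trend and all of plant 20 in it, plant as the unit of the trend, limma-voom without pool on the sums and features of the fit with pool, common feature sets for splits, comparisons of cells within or without shared pools, and the relations of plant values with length.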

Results

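The series measured transcripts of single male germinal cells of maize on the way to meiosis. Archesporial cells are the germinal initials of the anther, and they develop into pollen mother cells, which enter meiosis. The plants were of the inbred line W23 bz2. Anther length, which rises as the anther develops, served as the measure of stage. The data held 206 cells from 24 plants with anthers of 0.28 to 1.55 mm. Class A held 31 cells of 3 plants (0.28 to 0.32 mm), class B 71 cells of 6 plants (0.5 to 0.9 mm), class C 86 cells of 12 plants (1.04 to 1.45 mm) and class D 18 cells of 3 plants (1.5 to 1.55 mm). Summed UMIs per plant ranged from 428846 to 1486225 in class A, from 486197 to 1451884 in class B, from 61756 to 1454570 in class C and from 113315 to 1638691 in class D. A median of 77078.5 UMIs and 9063 features was counted per cell.

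The comparison of class D with class A asked which transcripts differed between the longest and the shortest anthers. Between these classes 1436 features were higher and 2000 lower in class D, which is 26.9% of the 12751 features tested (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 1435 were at least 2-fold higher and 1997 at least 2-fold lower, and 570 were at least 8-fold higher and 882 at least 8-fold lower by their fitted values. Among gene models with the prefix Zm00001d, 1012 rose and 1800 fell, of 10700 tested. Among MSTRG features, 397 rose and 200 fell, of 1988 tested. Among GRMZM5G features, 27 of 63 rose and 0 fell. A total of 2531 called features had a mean over 20 CPM in the higher class and no overlap between the plants of both classes, 1006 higher and 1525 lower in class D. By chance, a share of 10% of features has no overlap with 3 plants against 3. That share holds for all features and not for those already called, so it cannot be set against this count.

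The features with the largest changes went from no UMI to clear counts, or the reverse. MSTRG.18284 had no UMI in the 3 plants of class A and 114 ± 76.6 CPM (SD, n = 3) in class D, at least 114-fold higher on summed counts (adjusted p = 0.0105, edgeR). It stood at 1.02 ± 1.05 CPM (n = 6) in class B and 17.6 ± 40.04 CPM (n = 12) in class C. In class C, plant 9, with 100% of its cells of low complexity, had 137 CPM, and no other plant had more than 37.8 CPM. MSTRG.4803 also had no UMI in class A and reached 61.1 ± 44.2 CPM (n = 3) in class D, at least 90.6-fold higher (adjusted p = 0.00580, edgeR). Zm00001d028801 fell from 151 ± 54.3 CPM (n = 3) in class A to no UMI in class D, at least 102-fold lower (adjusted p = 0.00203, edgeR), with 43.8 ± 52.2 CPM (n = 6) in class B and 8.91 ± 11.1 CPM (n = 12) in class C. Zm00001d011246 fell from 55.1 ± 5.06 CPM (n = 3) to no UMI, at least 33.97-fold lower (adjusted p = 0.00293, edgeR). These bounds rest on single plants: plant 20 held 76.7% of the TMM-scaled library size of class D, 193 of 214 UMIs of MSTRG.18284 and 154 of 170 of MSTRG.4803, and without it they were 48.1-fold and 36.7-fold for the rises and 23.8-fold and 7.90-fold for the falls. Without plant 10, which held 54.4% of the scaled library size of class A, the rises were at least 52.03-fold and 41.3-fold. Fitted log2 fold changes, which for features with no UMI in a class depend on the prior count, went with library pool in the model from 9.49 (SE 2.56) to 3.52 (SE 1.67) for MSTRG.18284, from 8.79 (SE 2.10) to 3.10 (SE 1.64) for MSTRG.4803, from -9.97 (SE 1.94) to -4.99 (SE 0.934) for Zm00001d028801 and from -8.51 (SE 1.77) to -2.89 (SE 0.871) for Zm00001d011246. With it, MSTRG.18284 (adjusted p = 0.176) and MSTRG.4803 (adjusted p = 0.231) no longer passed. In the same limma-voom fit without pool their log2 fold changes were 5.64 (SE 0.980) and 5.32 (SE 0.886), so with pool the changes were smaller and the SEs larger, and those of Zm00001d028801 and Zm00001d011246 were -5.66 (SE 0.985) and -4.15 (SE 0.873). MSTRG.18284 also failed without plant 20 (adjusted p = 0.0517, edgeR). The number of calls fell to 1008 without plant 20 and to 1958 without plant 10, to 669 with library pool as a covariate (3174 in the same fit without pool) and to 504 with spike-in totals as library sizes. Scaling by library size alone gave 884 higher and 2243 lower, since it moved the median of all features from -0.08 to -0.45 on the log2 scale.

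**Figure D1:**
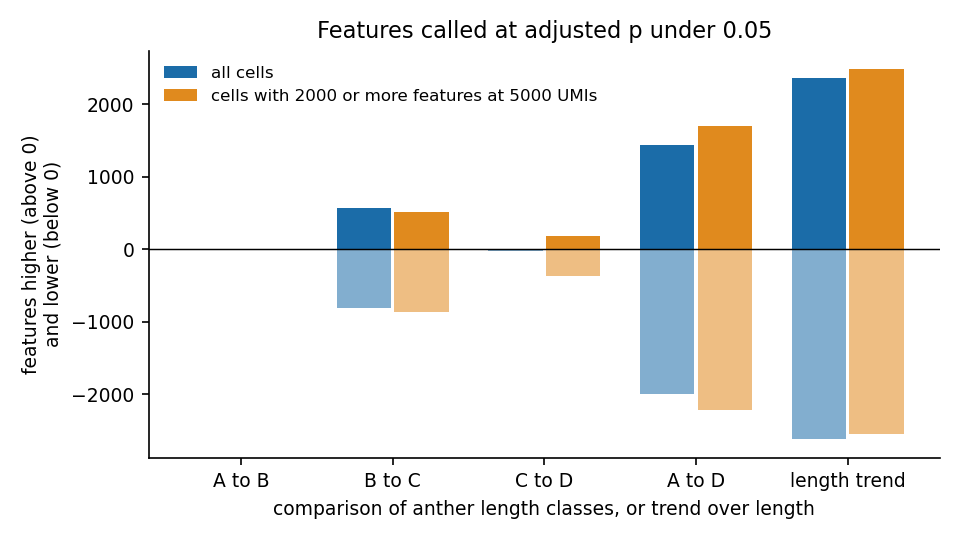
Features called in each comparison of length classes and in the trend over anther length, as counts of features higher (above 0) and lower (below 0) in the longer anthers at an adjusted p below 0.05. Blue bars are all 206 cells of 24 plants. Orange bars are the 170 cells with at least 2000 features in 5000 UMIs, from 21 plants, with 10 in class C and 2 in class D. From class C to class D, 29 and 548 features were called.

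**Figure D2:**
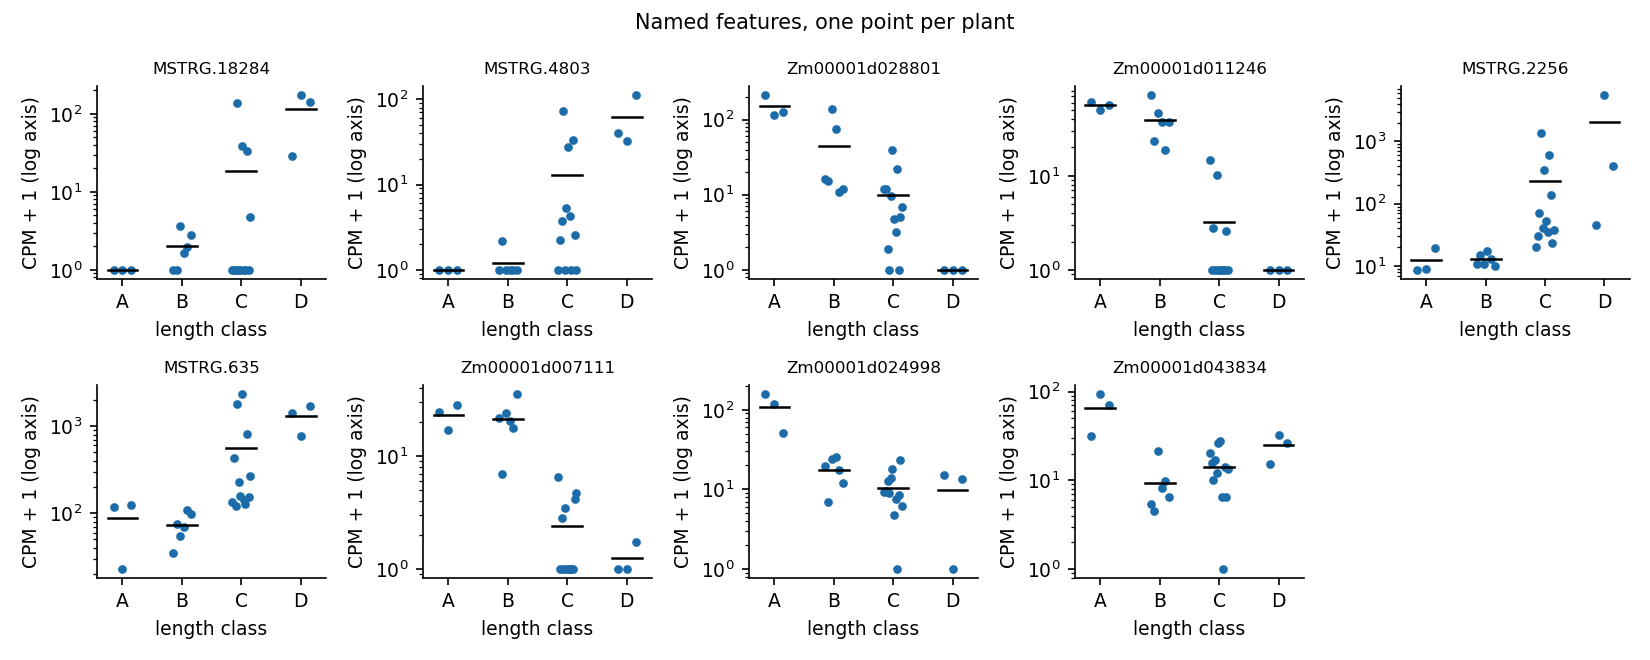
CPM + 1 on a log axis of the 9 named features, with 1 point per plant and a line at the class mean, for length classes A (3 plants), B (6), C (12) and D (3). MSTRG.18284 and MSTRG.4803 had no UMI in class A, and Zm00001d028801 and Zm00001d011246 had none in class D.

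The steps between neighbouring classes asked where along anther growth the transcripts differed. From class B to class C, 573 features rose and 807 fell, by a median of 1.72 on the log2 scale in either direction. The balance of rises and falls depended on the test: cells thinned to a common depth gave 346 rises and 176 falls of 3709 features tested, and the DESeq2 test 993 and 1004. Zm00001d gene models made up 347 of the rises and 750 of the falls, MSTRG features 209 and 57, and GRMZM5G features 17 and 0. MSTRG.2256 rose from 11.9 ± 2.89 CPM (SD, n = 6) to 228 ± 394 CPM (n = 12), a log2 fold change of 4.08 (SE 1.03, adjusted p = 0.0148, edgeR). MSTRG.635 rose from 72.6 ± 27.1 to 559 ± 741 CPM in the same plants (log2 fold change 2.95, SE 0.68, adjusted p = 0.00819, edgeR), and it stood at 1302 ± 479 CPM in class D (n = 3). Its mean in class C was carried by plants 15, 9 and 21 (2339.5 CPM, 1802 and 809), while the other plants of that class lay between 121 and 434 CPM. Zm00001d011246 fell from 38.3 ± 19.2 to 2.19 ± 4.48 CPM (log2 fold change -3.88, SE 0.58, adjusted p = 0.000404, edgeR). Zm00001d007111 fell from 20.1 ± 9.25 to 1.39 ± 1.91 CPM (log2 fold change -3.41, SE 0.51, adjusted p = 0.000392, edgeR). The mean of MSTRG.2256 in class C was carried by plants 9, 18 and 14 (1350 CPM, 596 and 345), of whose cells 100%, 100% and 75% had fewer than 2000 features in 5000 UMIs. Without such cells its log2 fold change was 1.95 (adjusted p = 0.0124, edgeR), and without plant 9 it was 3.14 (adjusted p = 0.0255, edgeR). In all, 6 rising and 90 falling features met the rule for named features in this step. MSTRG.2256 no longer passed with library pool in the model (log2 fold change 2.02, SE 1.09, adjusted p = 0.315, against 2.49, SE 0.631, in the same fit without pool, limma-voom) or with class borders 0.1 mm shorter (3.89, adjusted p = 0.0643, edgeR). The log2 fold change of MSTRG.635 was 2.25 with pool (adjusted p = 0.00602, limma-voom). That of Zm00001d011246 was -4.75 without plant 13 (adjusted p = 0.000154, edgeR), -5.62 with class borders 0.1 mm longer and -3.10 with borders 0.1 mm shorter. The number of calls was 417 with pool as a covariate (1999 in the same fit without pool) and 371 with spike-in totals as library sizes (204 higher and 167 lower), and it fell to 770 without plant 1, 470 without plant 3, 494 without plant 4 and 772 without plant 11.

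From class A to class B, 2 features fell and 0 rose. The count at an unadjusted p below 0.05 was 418, fewer than the 638 that chance alone gives among 12751 features, and DESeq2 also called 2 features. Zm00001d024998 fell from 109 ± 54.4 CPM (SD, n = 3) to 16.7 ± 7.202 CPM (n = 6), a log2 fold change of -2.67 (SE 0.44, adjusted p = 0.0161, edgeR). Zm00001d043834 fell from 64.6 ± 31.6 to 8.30 ± 6.20 CPM in the same plants (log2 fold change -2.88, SE 0.49, adjusted p = 0.0161, edgeR). Its mean in class D was 23.8 ± 8.95 CPM (n = 3). Both falls missed the threshold with library pool in the model, with class borders 0.1 mm shorter and with spike-in scaling (0 calls each, with 302, 366 and 211 features at an unadjusted p below 0.05, where chance alone gives 391, 638 and 638), while their log2 fold changes were -2.73, -2.50 and -2.44 for Zm00001d024998 and -2.62, -2.73 and -2.70 for Zm00001d043834. Across the alternatives that could be fitted the adjusted p ranged from 0.000239 to 1 and from 0.000469 to 1. The number of calls was 42 with limma-voom without pool, 0 without plant 1, 2, 11 or 12, 1 without plant 4, 10 or 24, and 4 without plant 3.

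From class C to class D, 7 features rose and 22 fell, 6 and 19 of them Zm00001d gene models and 1 and 3 of them MSTRG features. The count at an unadjusted p below 0.05 was 2786, where chance alone gives 638. The number of calls at an adjusted p below 0.05 varied with the plants and cells that entered. It was 548 (184 higher, 364 lower) without the 36 cells that had fewer than 2000 features in 5000 UMIs. This filter also removed plants 9, 18 and 19 whole, which left 10 plants in class C and 2 in class D. The number of calls was 2206 with class borders 0.1 mm shorter, 874 with the DESeq2 test, and 1169 with limma-voom without pool and 26 with it. It was 939 without plant 15, 580 without plant 9, 458 without plant 21, 287 without plant 14, 255 without plant 18, 79 without plant 16, 1 without plant 7, 13, 17, 19, 22 or 23, and 0 without plant 20 (1874 features at an unadjusted p below 0.05, where chance alone gives 685, edgeR).

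A slope over anther length was tested in all plants together, with 25 sums from 24 plants, since plant 20 had cells of 2 lengths and entered at each. With length, 2360 features rose and 2622 fell, of 10840 tested (edgeR quasi-likelihood test). Zm00001d gene models gave 1675 rises and 2388 falls of 9105 tested, MSTRG features 635 and 234 of 1680, and GRMZM5G features 50 and 0 of 55. Cells thinned to a common depth gave 730 rises and 634 falls of 2847 features tested. With each plant entered once at its mean length, 2259 rose and 2346 fell, of 10709 tested. The count of calls was 3753 without plant 20 at both lengths, it lay between 4224 and 5173 when each of the 25 sums was left out in turn, and it was 1603 with pool as a covariate (4131 in the same fit without pool).

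The kinds of identifier were tested as sets. MSTRG features as a group were higher than the other features from class B to class C (median log2 fold change 0.28, camera adjusted p = 9.97e-05), from A to D (0.71, adjusted p = 0.000154) and over length (0.51 per mm, adjusted p = 9.97e-05). With an estimated correlation these adjusted p were 0.0131, 0.0131 and 0.0219. From A to B and from C to D the MSTRG set passed at the fixed correlation (adjusted p = 0.0183 and 0.0408) and not at the estimated one (0.110 and 0.158). Without the cells of low complexity it passed at both correlations from A to B (0.0153 fixed, 0.0389 estimated) and at neither from C to D (0.116 and 0.183). GRMZM5G features had medians of 1.46, 2.37 and 2.08 from B to C, from A to D and over length (camera adjusted p = 1.09e-12, 1.56e-11 and 1.16e-11), but with an estimated correlation the adjusted p were 0.260, 0.275 and 0.266, and from A to B and from C to D they went from 0.0191 and 0.000118 to 0.651 and 0.474. With fry, the GRMZM5G set passed over length (adjusted p = 0.00823) and in no class comparison (0.064 or more). The MSTRG set passed with fry from B to C (0.0243), from A to D (0.00545) and over length (0.00195), and the Zm00001d set over length alone (0.00195). Camera sets a kind against all other features tested, which for Zm00001d were the MSTRG and GRMZM5G features. The Zm00001d result of camera is therefore the reverse side of theirs and not a separate one. This does not hold for fry, which tests each set on its own. With camera at the fixed correlation the Zm00001d set was lower than the others in all 5 comparisons (adjusted p at most 0.0266), though its median from A to B was 0.02. At the estimated one it passed over length (0.0172) and missed the threshold from A to B (0.287), B to C (0.0532), C to D (0.294) and A to D (0.0521). Without the cells of low complexity it passed at the estimated correlation from A to B (0.0172), B to C (0.0131), A to D (0.0104) and over length (0.00213), and not from C to D (0.110). From B to C, from A to D and over length the MSTRG and GRMZM5G medians were above 0 under each scaling run, and from C to D the MSTRG median of 0.11 turned to -0.08 with library size alone and to -0.24 with spike-in totals as library sizes. The Zm00001d median was -0.07 from B to C and turned to 0.23 with spike-in totals as library sizes, a scaling that moved the median of all features from -0.02 to 0.28. Without the cells of low complexity, GRMZM5G features gave 1, 16 and 35 rises and 0 falls of 56, 56 and 46 tested from B to C, from A to D and over length, and MSTRG features 105, 376 and 534 rises and 55, 224 and 221 falls of 2176, 2176 and 1667 tested.

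The share of UMIs from MSTRG features, as a mean over the cells of each plant, was 25.2% ± 1.30 (SD, n = 3) in class A, 26.9% ± 3.88 (n = 6) in class B, 41.2% ± 14.7 (n = 12) in class C and 45.7% ± 11.4 (n = 3) in class D. The share from GRMZM5G features was 1.39% ± 0.238, 1.44% ± 0.480, 3.38% ± 1.90 and 3.49% ± 1.27 in the same plants. For both shares the difference between classes A and D had an exact permutation p of 0.1 (two-sided), the smallest that 3 plants against 3 can give. Over all 24 plants the MSTRG share rose with length (Pearson's r = 0.620, permutation p = 0.00137, adjusted p = 0.00411; Spearman's rho = 0.810, permutation p = 2e-05, adjusted p = 6e-05). Without the 2 plants farthest from the median length r was 0.597. The GRMZM5G share rose too (r = 0.583, permutation p = 0.00278, adjusted p = 0.00556; rho = 0.738, permutation p = 6e-05, adjusted p = 0.00012; r = 0.561 without those 2 plants). Without the cells of low complexity the GRMZM5G relation no longer passed by rank (rho = 0.368, permutation p = 0.102, 21 plants) and had an unadjusted p just below 0.05 by Pearson's r (r = 0.434, permutation p = 0.0493), and the MSTRG relation passed by both (rho = 0.601, permutation p = 0.00437; r = 0.594, permutation p = 0.00426). No pool held more than 5 plants. The relations of these shares with length were computed without a pool term, so a part of library pools in them was not tested.

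Cells of low complexity, with fewer than 2000 features in 5000 UMIs, came mainly from longer anthers. They numbered 1 of 31 cells in class A, 5 of 71 in class B, 25 of 86 in class C and 5 of 18 in class D. The percent of a plant's cells that were of low complexity rose with length (r = 0.562, permutation p = 0.00392, adjusted p = 0.00588; rho = 0.720, permutation p = 8e-05, adjusted p = 0.00012; 24 plants; r = 0.544 without the 2 plants farthest from the median length). These 36 cells had a median of 29302 UMIs, 63.7% of UMIs from MSTRG features and 6.29% from GRMZM5G features. The other 170 cells had medians of 92194 UMIs, 25.1% and 1.27%. The log2 ratio of UMIs to spike-in UMIs showed no relation that passed the test with length over 24 plants (rho = 0.174, permutation p = 0.413, adjusted p = 0.496; r = 0.124, permutation p = 0.563, adjusted p = 0.676). Over means of splits per plant and pool its slope was 0.244 per mm, and 0.484 per mm with a pool term, neither of them tested. Over the 21 plants with complex cells, those cells alone gave rho = 0.688 (permutation p = 0.00065) and r = 0.657 (permutation p = 0.00159; 0.590 without 2 plants).

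**Figure D3:**
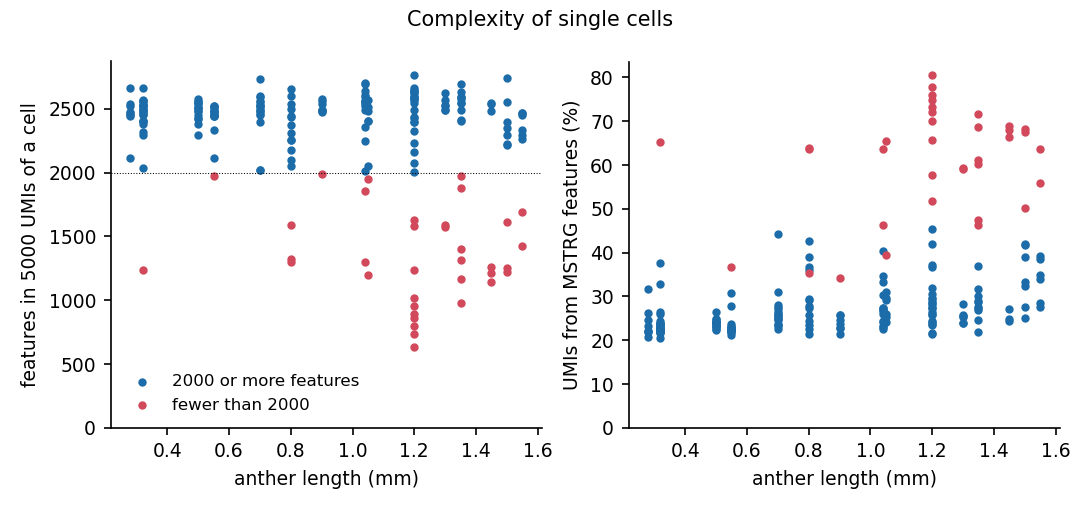
Features in 5000 UMIs of each cell (left) and percent of its UMIs from MSTRG features (right) against anther length in mm, with 1 point per cell. Red points are the 36 cells with fewer than 2000 features and blue points the other 170 cells; 30 of the red cells lie in classes C and D.

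Cells of the same plant were compared with cells of other plants of the class. Mean Spearman's rho across features was 0.531 within plants and 0.482 between plants, a difference of 0.0496 (one-sided permutation p = 1e-05, the smallest these permutations can give; features are not independent replicates). With cells thinned to a common depth the means were 0.527 and 0.464. Compared between cells of the same anther length alone, over complex cells at that depth, they were 0.531 and 0.498 (one-sided permutation p = 1e-04, the smallest these permutations can give). These permutations take no account of library pools, and the splits of a plant lay in 1 to 6 of the 28 pools. With 1 split per cell compared within a pool, the means were 0.507 and 0.498 (difference 0.00853, one-sided permutation p = 0.0633, with 377 pairs of cells within plants and 28 between), which did not pass. Over pairs of cells that shared no pool the means were 0.521 and 0.496, not tested. A difference between plants apart from pools was therefore not shown.

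The splits of a cell gave a technical replicate for 185 cells. Across features with a UMI in either split, the median r of log2(CPM + 1) was 0.0250, with cells from -0.573 to 0.567, and the median rho was 0.250. For splits of different cells of the class the median r was 0.0045, and in 101 of 185 cells the own split matched better than the mean of other cells. The feature set of this measure changed with each pair and left out features absent from both, and r followed depth, with a median of -0.258 in the 25% of cells with fewest UMIs and 0.304 in the 25% with most. Over a common set of 10386 features, chosen after the data were examined, the median r was 0.482 for the same cell and 0.412 for other cells, and the own split matched better than the mean of other cells in 178 of 185 cells.

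On the leading axis of variation, examined after the data were seen, among 165 complex cells of 21 plants, which carried 11.3% of the variance over 7451 features, plants fell into separate clusters. The means of 17 plants lay between -31.0 and 19.9, and those of 4 plants between 60.4 and 83.4. These 4 were plants 15 and 21 of class C and plants 16 and 20 of class D. The lowest cell of the 4 plants stood at 53.4 and the highest cell of the others at 32.7. Among the 17 plants the mean position rose with anther length (r = 0.950, rho = 0.931, permutation p = 1e-05 for both, the smallest these permutations can give, adjusted p = 6e-05; r = 0.947 without the 2 plants farthest from the median length). The 4 plants were too few for a correlation of their own.

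**Figure D4:**
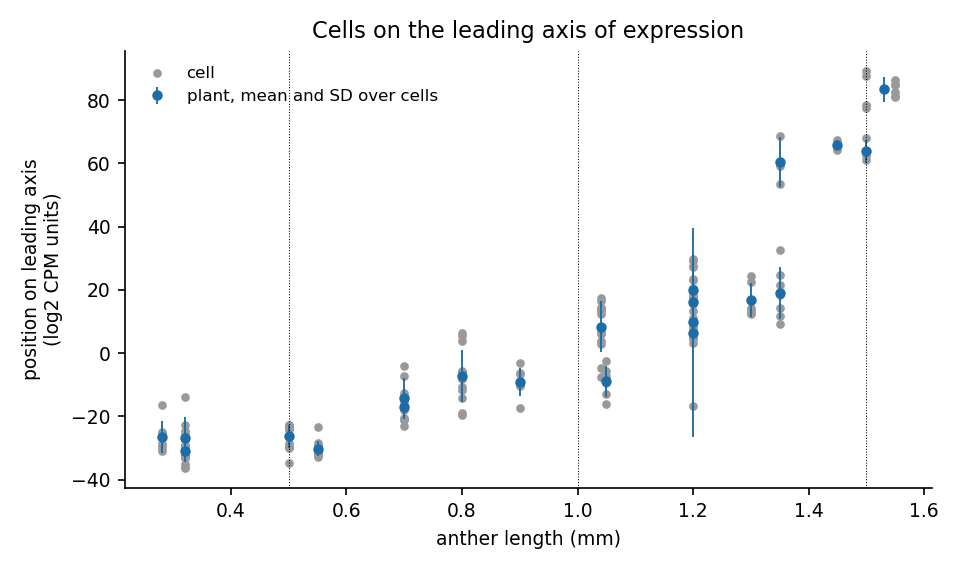
Position on the leading axis of expression (log2 CPM units) against anther length in mm for 165 cells of 21 plants. Plants 9, 18 and 19 had no complex cell and are not shown. Grey points are cells, blue points with bars the mean and SD over the cells of a plant, and dotted lines the class borders; the plants from 1.35 mm upward with means of at least 60.4 stand apart from the rest, and another plant of 1.35 mm lies at 18.9.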

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

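A result is given here where the highest or lowest plant of a class stood far from the nearest other plant by Dixon's criterion. Of 15 groups of 4 to 10 plants tested, 3 met it, where chance gives about 1 in 20. Classes A and D held too few plants for it, and class C too many except for positions on the leading axis. Extreme plants in these classes could therefore mostly not be flagged. In class B, plant 8 (0.8 mm) had the highest share of UMIs from MSTRG features, 34.3%, with the next plant at 27.7%. In that plant 3 of 16 cells were of low complexity, and its complex cells alone gave 29.7%. MSTRG.4803 had 1.19 CPM in plant 2 of class B and 0 in the other 5 plants, a value that rests on 1 UMI. With 0 in all other plants any value meets the criterion, so the rate given for chance does not hold there. Zm00001d043834 had 20.3 CPM in plant 3 of class B and at most 8.88 CPM in the other 5 plants.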

How the results depend on the processing

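Alternatives chosen after the data were examined were spike-in scaling, Zm00001d features alone, the complexity filter (cells with at least 2000 features in 5000 UMIs), the common feature sets for splits, the comparisons of cells within or without shared pools, plant as the unit of the trend, limma-voom without pool on the sums and features of the fit with pool, leaving out plants of classes B and C, and each left-out plant of the trend. No named feature changed sign in any alternative run: 217 of their values under alternatives kept their direction and passed while 24 kept their direction and did not pass. Each named feature had no overlap between the plants of the classes compared, so a change of sign was hardly possible. The kept directions are therefore no separate support. With borders 0.1 mm longer, which gave 3 classes, the values counted for A to D compare the longest class, of 13 plants, with the shortest. With pool in the model, 2474 of 2481 calls from A to D and 3821 of 3869 of the trend that could be fitted kept their sign. The cause of a changed count was not tested unless stated. From class A to class B (2 calls), the count was 7 with no filter, 18 with borders 0.1 mm longer, 1 with the complexity filter, 42 with limma-voom without pool and 0 with spike-in scaling, thinned cells, library pool as a covariate or borders 0.1 mm shorter (211, 143, 302 and 366 features at an unadjusted p below 0.05, each fewer than the 638, 185, 391 and 638 that chance alone gives; the DESeq2 test called 2). From B to C (1380) it was 371 with spike-in scaling, 522 with thinned cells (346 higher, 176 lower, where all cells gave 573 and 807), 417 with pool and 491 with borders 0.1 mm shorter. From C to D (29) it was 177 with DESeq2 size factors (24 higher, 153 lower), 1 with library size alone, 169 with no filter, 0 with spike-in scaling (1381 at an unadjusted p below 0.05, by chance 638), 874 with the DESeq2 test, 1169 with limma-voom without pool (26 with pool), 1470 with plant and length as the unit, 60 with cells of at least 10000 UMIs, 548 with the complexity filter, 258 with Zm00001d features alone and 2206 with borders 0.1 mm shorter, which put 5 plants in class D. From A to D (3436) it was 504 with spike-in scaling, 976 with thinned cells and 669 with pool. The trend (4982) gave 7655 with no filter, 1364 with thinned cells (730 higher, 634 lower, where all cells gave 2360 and 2622) and 1603 with pool, and library size alone split it into 1600 higher and 2902 lower. Thinning left 3709 features to test between classes and 2847 over length, and the pool fit 7817, fewer than the 12751 and 10840 tested otherwise. Spike-in scaling moved the median log2 change of all features to 0.27 from A to B, 0.28 from B to C and -0.53 from C to D.

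Without each plant in turn the counts ranged from 0 to 4 from A to B, 470 to 1857 from B to C, 0 to 939 from C to D, 1008 to 3026 from A to D and 3753 to 5173 for the trend. Splits of a cell, as means over plants, had r of 0.0367, and 0.525 with at least 10 UMIs per feature, 0.318 with log2(CPM + 10), 0.497 over a common feature set and 0.586 over all features. Their rho of 0.233 became 0.538, 0.508 and 0.528 with at least 10 UMIs, the common set and all features, and the r of the same cell minus that of others went from -0.0016 to 0.218 with at least 10 UMIs. With the complexity filter, rho with length was 0.688 for UMIs per spike-in UMI (passing) and 0.368 for the GRMZM5G share (not passing). Within a pool, the rho of cells of a plant exceeded that of other plants by 0.00853, which did not pass (one-sided permutation p = 0.0633), with 28 pairs between plants left.

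The 3 classes with borders 0.1 mm longer held 5, 6 and 13 plants and gave no step from C to D. No paired analysis was possible because each plant gave cells of a single class. Spike-in scaling was not run for the trend, and comparisons of genotypes and gene lists were not run. In simulated data of these depths 2-fold changes were recovered in 3.39%, 12.9%, 7.58% and 1.54% of cases from A to B, B to C, C to D and A to D, so changes of that size were mostly not detectable.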

Other observations

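All tests in this part were chosen after the data were seen, except the counts of calls under other groupings of the plants and the fit with library pool as a covariate. The fit without pool, and the use of kept signs and sizes to judge pools, were also chosen after the data were seen. Cells of the same plant differed in the same features in both of their splits. With every split at 10000 UMIs, the deviation of a feature from its plant's mean had r of at least 0.5 between splits for 57 of 696 features in class A, 42 of 769 in class B, 82 of 760 in class C and 182 of 656 in class D. When splits were shuffled among the cells of a plant 100 times, the highest counts were 28, 3, 28 and 120. Shuffles within plants took no account of library pools. An effect of pools on both splits of a cell could therefore give such agreement, here and in the axis positions and feature group described below, and it was not tested. The class D values come from 9 cells of 1 plant. Positions of cells on the leading axis also kept their order within plants between splits (r = 0.825, rho = 0.747, r = 0.802 without the 2 farthest cells, 141 cells), with a permutation p of 1e-04, the smallest the shuffles can give. After removing features per 5000 UMIs and depth r was 0.718, and the position itself had r = -0.643 with features per 5000 UMIs.

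A group of 20 features that varied together between cells of class A plants had a mean cross-split r of 0.437 there, where it was selected, which is no independent value. In the cells of class B it was 0.115, where the highest of 1000 random groups reached 0.0855, and in class C it was 0.324, where random groups reached 0.192. In class D it was 0.163 over the 17 features measured, and 4 of 1000 random groups were as high. The summed level of the group had r of 0.339, 0.584, 0.458 and 0.641 with log2 UMIs per cell within plants in classes A to D, and of -0.024, 0.677, 0.0656 and 0.619 with features per 5000 UMIs, so that in classes B and D it went with the complexity of the cell. The spread of cells on the leading axis within plants showed no relation with anther length that passed the test (rho = 0.115, permutation p = 0.648, adjusted p = 0.648; r = 0.0907, permutation p = 0.716; 18 plants).

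The number of calls between classes may reflect chance, cells of low complexity or library pools. For chance, 1 of 84 regroupings of the plants gave as many calls as from class A to class B (2, highest other 0), the real grouping. That share is the smallest these regroupings can give. It rests on 2 calls, and 418 features had an unadjusted p below 0.05 (edgeR), where chance alone gives 638. For this step it argues at most weakly against chance. From B to C, 1 of 100 gave as many (1380, highest other 549), again the real grouping, which argues against chance. From C to D, 11 of 100 gave as many as the 29 real calls, so chance cannot be excluded. Among them, the regrouping with plants 14, 18 and 19 as the group of 3 called 2214, which points to a structure of the samples. Of the cells of these plants 75%, 100% and 100% were of low complexity, but the regroupings were not repeated without such cells, so what this structure is stays open. On the leading axis, plants 15 and 21 of class C lay in the cluster of plants 16 and 20 of class D. Class C therefore held plants of both clusters. Whether this mix lowered the number of calls from C to D was not tested. From A to D the 10 regroupings possible are too few for a share under 0.05 (3436 calls, highest other 0). Without the cells of low complexity, 1103 of the 1380 calls from B to C and 3120 of the 3436 from A to D were also made with the same sign, which argues against these cells as the whole cause. With pool in the model, 100% of the called features that could be fitted kept their sign from B to C and 99.7% from A to D, at a median of 0.834 and 0.710 of their size in limma-voom on the same sums and features without pool, which argues against pools as the whole cause. The calls were 1999 and 3174 in that fit without pool and 417 and 669 with it, where SEs were a median of 1.338 and 1.205 times as large. Pools as a part of the cause, and stage itself, stay open.

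Cells of low complexity, more frequent in plants with longer anthers, may come from particular pools or from cells of which less RNA was recovered. Over plants and pools, the percent of splits from such cells rose by 37.5 per mm, and by 19.8 per mm with a pool term (permutation p = 0.480), so pools stay open as a cause. In the 15 plants that held both kinds of cell, the ratio of UMIs to spike-in UMIs was lower in the cells of low complexity in 15 of 15, with a mean log2 difference of -2.35 ± 0.965 (SD, 15 plants), which is consistent with less RNA recovered from these cells. The MSTRG share was higher in 15 of these plants and the GRMZM5G share in 15. Whether damaged protoplasts, cells of another type or a stage with less RNA gave these values was not tested, since no marker list could be resolved.

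The gap on the leading axis between 4 plants and the other 17 may come from library pools, counting depth or stage. For pools, the axis and the sides were taken from the splits outside the 3 pools that held plants of both sides, and the splits within these pools were placed on that axis. There the 9 splits of plant 20 stayed apart from those of plants 2, 13 and 23 by at least 45.97 within each pool, where the largest SD of a plant's splits was 8.26, which argues against pools for plant 20. Plant 21, which gave no split to that axis, stayed apart by at least 12.97 with its 5 splits from plants 2 and 13 in the same pools. These 5 splits came from 3 cells and are not independent, so for plant 21 this argues only weakly against pools. For plants 15 and 16, pool and stage cannot be told apart, since 0 of them had splits in these pools. With every cell at 10000 UMIs the sides stayed apart by 18.03, which argues against counting depth. The 4 plants had anthers of 1.35, 1.5, 1.45 and 1.53 mm on average, while another plant of 1.35 mm lay at 18.9, so length alone did not place a plant. Plants 9 (1.35 mm), 18 (1.45 mm) and 19 (1.5 mm) had no complex cell and so no position on the axis. A step in the transcript programme near this length is a candidate explanation that was not tested, because no stage other than length is given.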
